A study of Mus musculus with 7 samples.

How the data were processed

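RNA of mouse sperm was measured on 7 expression arrays. Per the labels, 1 array held C57BL/6 sperm pooled from 5 males. TG3 and nonTG3 had 3 arrays each, and every one of these held a pool from 4 males. TG3 males carried a KDM1A transgene passed on through heterozygous males bred to C57BL/6 females, and nonTG3 males were littermates that had not inherited it, both in generation 3. KDM1A is a histone lysine demethylase. RNA was amplified and labelled with an Affymetrix kit for whole transcripts, per the labels' protocols. The labels do not say whether a male entered more than 1 pool, so p-values measure the spread between these pools.

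The deposited values are log2 intensities made by the authors with RMA, which corrects background, normalizes arrays to a common distribution and summarises the probes of a probe set. Per the submitters' processing notes, the tools were R 3.1.0, oligo, RMA and limma. A filter on probe sets, a genome build and scan batches are not given in the sources used here. The table held 33604 probe sets. The array medians lay between 3.52 and 3.61, and the values were not centred per gene. RMA's summary step gave exactly equal values on several arrays for many probe sets: 30.9% of those tested had 4 or fewer distinct values on the 6 arrays of the transgenic line. Arrays have no read depth, and their number limits the precision.

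Probe sets were named from the platform annotation. Of all probe sets, 23493 had 1 gene symbol, 1801 had several and 8310 had none. Those with 1 symbol were tested and covered 22154 distinct symbols. Entrez identifiers matched 23300 of them to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names alone. No coordinates are given, because the build behind the array annotation is not stated in the sources used here.

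All tests were computed on the log2 values with limma 3.58.1 in R 4.3.3. One model with a mean per group was fitted to all 7 arrays and moderated with eBayes, and p-values were adjusted by Benjamini-Hochberg over the 23493 probe sets of each contrast. The contrasts were TG3 against nonTG3, TG3 against C57BL/6, nonTG3 against C57BL/6, and the mean of TG3 and nonTG3 (the line) against C57BL/6. The lone C57BL/6 array adds nothing to the estimate of spread and is assumed to vary like the arrays of the other groups. The model had 4 residual and 1.65 prior degrees of freedom. A probe set was called at an adjusted p under 0.05.

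Before the data were examined, 32 gene lists, the models, most alternatives and the rule for naming genes were fixed. The rule took, per contrast, the 10 largest increases and the 10 largest decreases among called probe sets whose groups did not overlap. Where none passed, it took the 5 smallest p-values in each direction. It left out genes with predicted or clone names, and added Kdm1a and up to 4 members with the smallest p of each list described. Each gene entered a list through its probe set with the highest mean. Lists were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way.

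The steps were tested on simulated data with 100 changed genes per size among 23493. Noise was drawn independently for each gene and array. For TG3 against nonTG3, 52% of genes changed by 1 log2 unit and 92% of those changed by 2 were called, with 9 false calls. For the line against C57BL/6, the shares were 23% and 82%, with 3 false calls. A simulated shift of 0.5 log2 units in the ribosomal protein list was called, along with 0 other lists. Genes on real arrays can vary together, so these shares and false calls need not hold for the data.

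Alternatives covered other normalizations (a repeated quantile normalization, median centring and cyclic loess), eBayes with a trend or robust prior, array weights, filters on dim probe sets, all probe sets of the table, other thresholds, each array of the line left out in turn, fits on fewer groups, and the replicate number as a block. Alternatives that left out both arrays with the lowest mitochondrial RNA, or probe sets with 4 or fewer distinct values on the line's arrays, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.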

Results

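Sperm RNA was compared between C57BL/6 mice, males of a KDM1A transgenic line that carried the transgene (TG3) and their littermates without it (nonTG3). There was 1 array of C57BL/6 and there were 3 each of TG3 and nonTG3, every array a pool of males. Values are log2 RMA intensities as deposited by the authors, and the C57BL/6 values have no replicates. Pearson's r across probe sets, which are not independent replicates, was 0.942 to 0.984 between TG3 and nonTG3 arrays and 0.944 to 0.958 between C57BL/6 and TG3.

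TG3 against nonTG3 asks how sperm RNA differs with the transgene among littermates. Kdm1a, the mouse gene for this demethylase, read 5.20 ± 0.12 (SD, n = 3) in TG3 and 5.20 ± 0.12 (SD, n = 3) in nonTG3. The C57BL/6 array read 5.64. Replicates 2 and 3 of both TG3 and nonTG3 had exactly equal values of 5.27, so ties limit what this comparison can show. A two-sided exact permutation test between TG3 and nonTG3 gave p = 1, where 0.1 is the smallest p that 3 against 3 allows. Whether this probe set reads the transgene's own RNA is not given in the sources used here, so the level checks the labels only in part.

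No single gene passed the test between TG3 and nonTG3. limma called 0 of 23493 probe sets, with a smallest adjusted p of 0.923, and 559 had an unadjusted p under 0.05 where chance alone gives 1175. Without both arrays with the lowest mitochondrial RNA, TG3 replicate 1 and nonTG3 replicate 3, the 559 became 1155. The smallest p-values among genes with higher means in TG3 belonged to Mrpl50, a mitochondrial ribosomal protein, Lce6a, Klk1b24, Sprr2h and Ssx9. Mrpl50 read 4.87 ± 0.11 (SD, n = 3) in TG3 and 4.24 ± 0.12 (SD, n = 3) in nonTG3, at a limma adjusted p of 0.923. Those with lower means in TG3 were Mx2, an interferon-induced GTPase, Tfb2m, a mitochondrial transcription factor, Clec18a, Tas2r129, a taste receptor, and Prickle2. Mx2 read 2.93 ± 0.05 (SD, n = 3) in TG3 and 3.40 ± 0.08 (SD, n = 3) in nonTG3, also at a limma adjusted p of 0.923. Mx2, Sprr2h, Ssx9, Tfb2m and Tas2r129 averaged below the lowest array median of 3.52 in both TG3 and nonTG3. Whether such values lie above background was not measured.

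At the preset correlation camera called 5 of 32 lists, all higher in TG3: cytosolic ribosomal proteins, oxidative phosphorylation, proteasome subunits, leukocytes and epididymal epithelium. Of their members 0 passed singly, over all genes or adjusted over the list alone. No list was called with an estimated correlation (smallest adjusted p = 0.969 with an estimated correlation) or by fry, which gave an adjusted p of 0.814 for each of the 5. The median change of 68 cytosolic ribosomal proteins was 0.34 log2 units, with 57 members higher and 11 lower. Rplp1 read 10.50 ± 0.30 (SD, n = 3) in TG3 and 9.67 ± 0.38 (SD, n = 3) in nonTG3. Among 76 nuclear genes of oxidative phosphorylation the median was 0.30 and 65 were higher, and Ndufb10, of complex I, read 5.05 ± 0.14 (SD, n = 3) against 4.67 ± 0.16 (SD, n = 3). Among 38 proteasome subunits the median was 0.20 and 32 were higher, among them Psmb5. Medians were 0.12 for leukocyte genes, such as C1qb, and 0.11 for genes of the epididymal epithelium, such as Krt19. The leukocyte median was 0.039 without TG3 replicate 1 and 0.064 without nonTG3 replicate 2. The epididymal median was 0.054 without TG3 replicate 1, 0.062 without nonTG3 replicate 3 and 0.24 without nonTG3 replicate 1. The list means were uneven within nonTG3: ribosomal proteins averaged 6.58, 5.92 and 6.31 on nonTG3 replicates 1, 2 and 3, and 6.71, 6.60 and 6.51 on the TG3 replicates. Mitochondrially encoded genes, at 11.24 on the C57BL/6 array, averaged 8.80, 11.44 and 11.51 on TG3 replicates 1, 2 and 3 and 11.55, 9.98 and 8.91 on nonTG3. Without nonTG3 replicate 2 the median change was 0.14 for ribosomal proteins, 0.13 for oxidative phosphorylation and 0.19 for proteasome subunits. Without TG3 replicates 2 or 3 camera called 9 and 8 lists, without nonTG3 replicate 1 it called 9, and without nonTG3 replicate 2 it called 3, leaving leukocytes and epididymal epithelium uncalled at adjusted p of 0.0934 and 0.176. Those 2 lists were also uncalled without TG3 replicate 1, at an adjusted p of 0.308 for each, and epididymal epithelium without TG3 replicate 3 or nonTG3 replicate 3, at 0.0571 and 0.259.

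**Figure D1:**
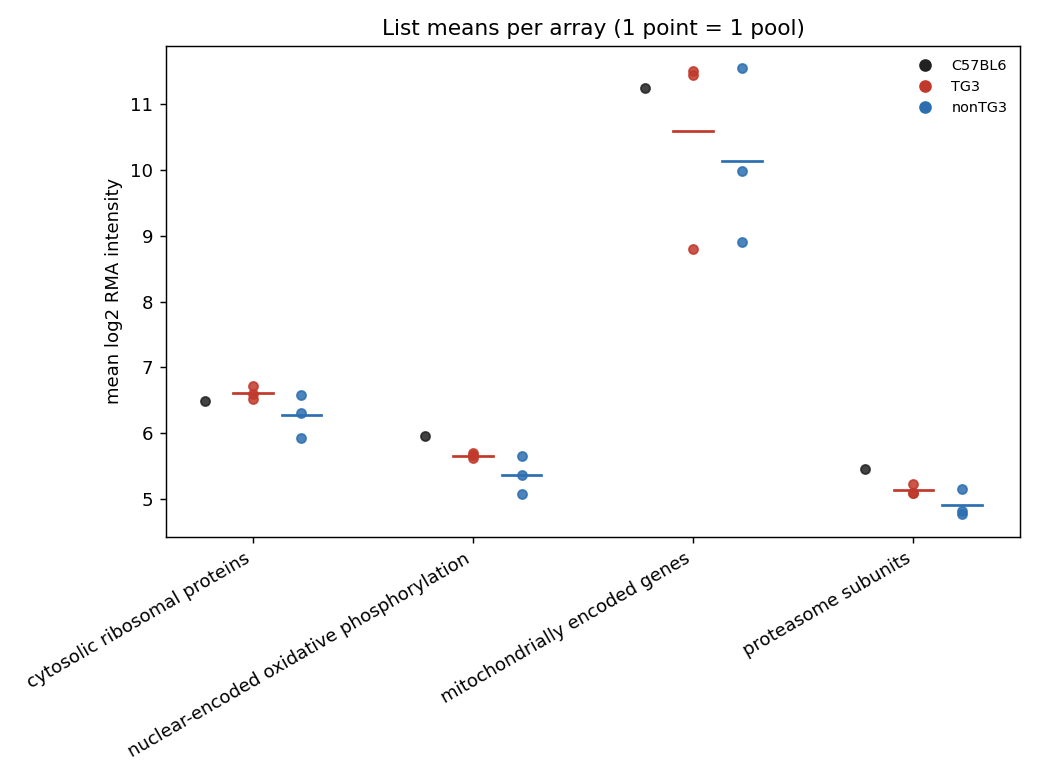
Mean log2 RMA intensity over the members of 4 gene lists, 1 point per array (black C57BL/6, red TG3, blue nonTG3), with a bar at the mean of each group of 3. Ribosomal proteins lie at 5.92 on nonTG3 replicate 2 and between 6.31 and 6.71 on the other 5 arrays of the line.

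Both kinds of male from the line differed from the C57BL/6 array. Some RNAs of late spermatogenesis, of meiotic cells and of Sertoli and Leydig cells were lower in the line: 17 of 36 acrosome, 8 of 18 chromatin, 10 of 53 flagellum, 8 of 46 meiotic and 6 of 27 Sertoli and Leydig genes. Fry, which asks whether the genes of a list move on balance one way, called all 5 lists (adjusted p of 0.00886 to 0.0419). Camera, which compares a list with other genes, called 15 of the 32 lists at the preset correlation, 10 lower and 5 higher. It called none of these 5 lists with an estimated correlation (adjusted p of 0.287 to 0.317 with an estimated correlation). Of 23493 probe sets, limma called 710 between the line and C57BL/6, 670 lower and 40 higher. Among them 575 differed by at least 1 log2 unit and 30 by at least 3 log2 units. The largest decrease was that of Defb19, a beta-defensin, which read 9.18 in C57BL/6 and 2.92 ± 0.05 (SD, n = 6) in the line (limma adjusted p = 4.89e-05). The spread behind this p comes from the line's arrays alone, and the 3 nonTG3 arrays had exactly equal values of 2.95. Whether values below the lowest array median of 3.52 lie above background was not measured, so readings, and no fold or log2 change, are given for a single gene that lay below it in the line or, among increases, on the C57BL/6 array. H2bc1, a testis histone, read 9.08 against 4.34 ± 0.57 (SD, n = 6). Cst9, a Sertoli cell cystatin, read 7.66 against 2.94 ± 0.36 (SD, n = 6), and Cyp17a1, an enzyme of androgen synthesis in Leydig cells, read 6.56 against 2.40 ± 0.25 (SD, n = 6). The mitochondrial protein Spata19, the dynein light chain Dynlrb2 and Pdcl2 fell by 3.67 to 4.06 log2 units. The testis subunit Cox7b2, Rasl2-9 and Tsx read 7.33, 6.84 and 6.96 in C57BL/6 and averaged 3.05, 2.67 and 3.26 in the line.

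Some RNAs for proteins that package sperm DNA were lower in the line, as were some for the acrosome and tail. Of 18 sperm chromatin genes 8 fell, with a median change of -1.20. Tnp1, a transition protein, fell from 12.40 to 9.51 ± 0.21 (SD, n = 6), and Prm1, a protamine, from 11.64 to 10.19 ± 0.09 (SD, n = 6). Prm3 fell 3.12-fold. Of 36 acrosome and egg-binding genes 17 fell, with a median of -1.38. Spaca1 and Acrv1 of the acrosome fell 7.23-fold and 6.63-fold, and the hyaluronidases Hyal5 and Spam1 fell from 5.17 and 3.96 to 2.28 and 1.92. Of 53 genes of the flagellum and motility 10 fell, with a median of -0.63, among them Meig1 (8.33-fold), Cylc2, the sperm sodium-proton exchanger Slc9c1 and the sperm lactate dehydrogenase Ldhc (5.76-fold). Smcp and Odf1, abundant tail RNAs chosen after their values were seen, had changes of -0.085 and -0.039 log2 units, at limma adjusted p of 1. Adjusted over the list alone, 11 chromatin, 26 acrosome and 20 flagellum genes were lower. With an estimated correlation the adjusted p was 0.287 for the chromatin and acrosome lists and 0.317 for the flagellum.

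Of 46 meiotic genes 8 fell, 14 when adjusted over the list alone, with a median of -0.35 (adjusted p = 0.287 with an estimated correlation). Of the synaptonemal complex, Sycp2 fell from 6.26 to 3.39 and Syce3 fell 4.94-fold, Smc1b, a meiotic cohesin, fell 4.95-fold, and Tdrd6, of the chromatoid body, fell 5.59-fold. Of 26 genes of spermatogonia and early germ cells 0 were called and the median was 0.10. Of 27 Sertoli and Leydig cell genes 6 fell, also 6 adjusted over the list alone, with a median of -0.092 (adjusted p = 0.287 with an estimated correlation). At the preset correlation camera called this list over all probe sets, but not over those with a mean at or above the median (adjusted p = 0.265). Its median was -0.15 without TG3 replicate 1 and -0.18 without nonTG3 replicate 1. Besides Cyp17a1 and Cst9 the genes that fell included Hsd3b6, a steroid dehydrogenase that fell from 4.39 to 2.05, and the defensin Defb36, which fell 4.69-fold. Cyp11a1 was read by a pair of probe sets that differed: 1 read 4.74 in C57BL/6 and 2.71 in the line (limma adjusted p = 0.00552), and the other 3.20 and 3.21 (limma adjusted p = 1).

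**Figure D2:**
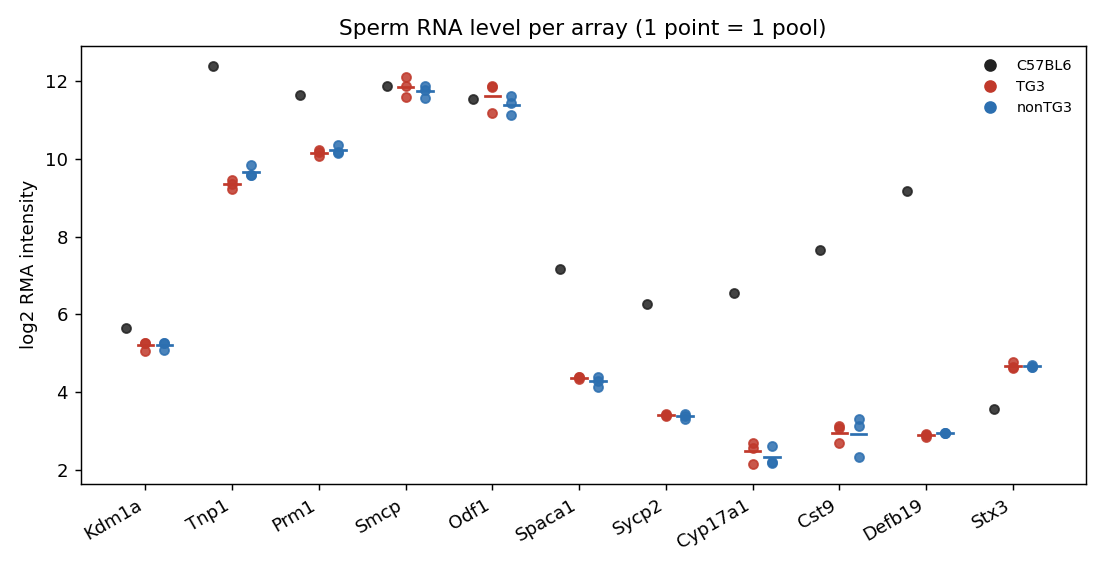
Log2 RMA intensity of 11 genes, 1 point per array (black C57BL/6, red TG3, blue nonTG3), with a bar at the mean of each group of 3. Tnp1, Prm1, Spaca1, Sycp2, Cyp17a1, Cst9 and Defb19 lie lower on all 6 arrays of the line than on the C57BL/6 array, while Kdm1a has the same mean of 5.20 in TG3 and nonTG3.

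Lists of energy metabolism, translation and protein turnover also held called members, where 670 of all 23493 probe sets tested were lower. The called counts for oxidative phosphorylation and proteasome subunits lay near that share. Of 76 oxidative phosphorylation genes 3 fell, including the testis subunits Cox6b2 (4.42-fold) and Cox7b2 (median -0.26, adjusted p = 0.371 with an estimated correlation). In translation control 7 of 42 fell, including Papolb, Pabpc6 and Ybx2 (median -0.17, adjusted p = 0.371 with an estimated correlation). In ubiquitin and spermatid protein turnover 7 of 32 fell, including Rnf133 and Rnf148 (median -0.081, adjusted p = 0.317 with an estimated correlation). In heat shock 4 of 31 fell, including Dnajb7 and Hspa1l (median -0.28, adjusted p = 0.371 with an estimated correlation). Of 38 proteasome subunits 1 fell, Psma6 (median -0.27, adjusted p = 0.371 with an estimated correlation). Adjusted over the list alone the counts were 13, 9, 9, 6 and 5. Without TG3 replicate 1 the median was -0.11 for translation control and -0.19 for ubiquitin, without TG3 replicate 2 it was -0.26 and -0.13, and without nonTG3 replicate 1 it was -0.26 for translation control and -0.53 for heat shock. Over all alternatives the medians ran from -0.37 to -0.15 for oxidative phosphorylation, -0.33 to -0.071 for translation control and -0.22 to -0.048 for ubiquitin. For heat shock the range was -0.53 to -0.19 and for proteasome subunits -0.35 to -0.13. Oxidative stress defence was not called as a list over all arrays, but was without nonTG3 replicate 1 (adjusted p = 0.0177), and 5 of its 32 members fell, including Nme8 and Txndc2. At the preset correlation camera also called 5 lists higher in the line, with medians of 0.26 for fibroblasts, muscle and vessels, 0.20 for developmental signalling ligands, 0.13 for Hox genes, 0.12 for developmental transcription factors and 0.084 for olfactory and vomeronasal receptors. On the C57BL/6 array the ligands, Hox genes, transcription factors and receptors averaged 3.52, 3.76, 3.48 and 1.93, against an array median of 3.52. Whether such dim signals lie above background was not measured. Of the receptors 3 rose and 1 fell, but 0 adjusted over the list alone, and Olfr51, Olfr283 and Olfr801 lost their calls in 5 of the 6 fits without 1 array and Vmn1r69 in 2. In the other 4 lists 0 members were called. With an estimated correlation their adjusted p were 0.754, 0.287, 0.317, 0.317 and 0.569, and fry called the signalling ligands alone among them (adjusted p = 0.0403). Genes of fibroblasts, muscle and vessels averaged 5.12 and 4.97 on TG3 replicate 1 and nonTG3 replicate 3, the arrays with the lowest mitochondrial RNA, against 4.30 to 4.51 on the other 4 arrays of the line and 4.33 on C57BL/6. Without both arrays their median was 0.13 and the list was not called (adjusted p = 0.126), nor was it without TG3 replicate 1 (median 0.16, adjusted p = 0.0731) or nonTG3 replicate 3 (adjusted p = 0.102). Hox genes were not called without TG3 replicate 3 (adjusted p = 0.0608) and had a median of 0.076 without nonTG3 replicate 2, and the receptors were not called without TG3 replicate 1, TG3 replicate 3 or nonTG3 replicate 2 (adjusted p of 0.0539, 0.101 and 0.0529). Over all alternatives run for these lists, other normalizations included, the median ran from 0.069 to 0.16 for Hox genes and from 0.029 to 0.11 for the receptors.

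**Figure D3:**
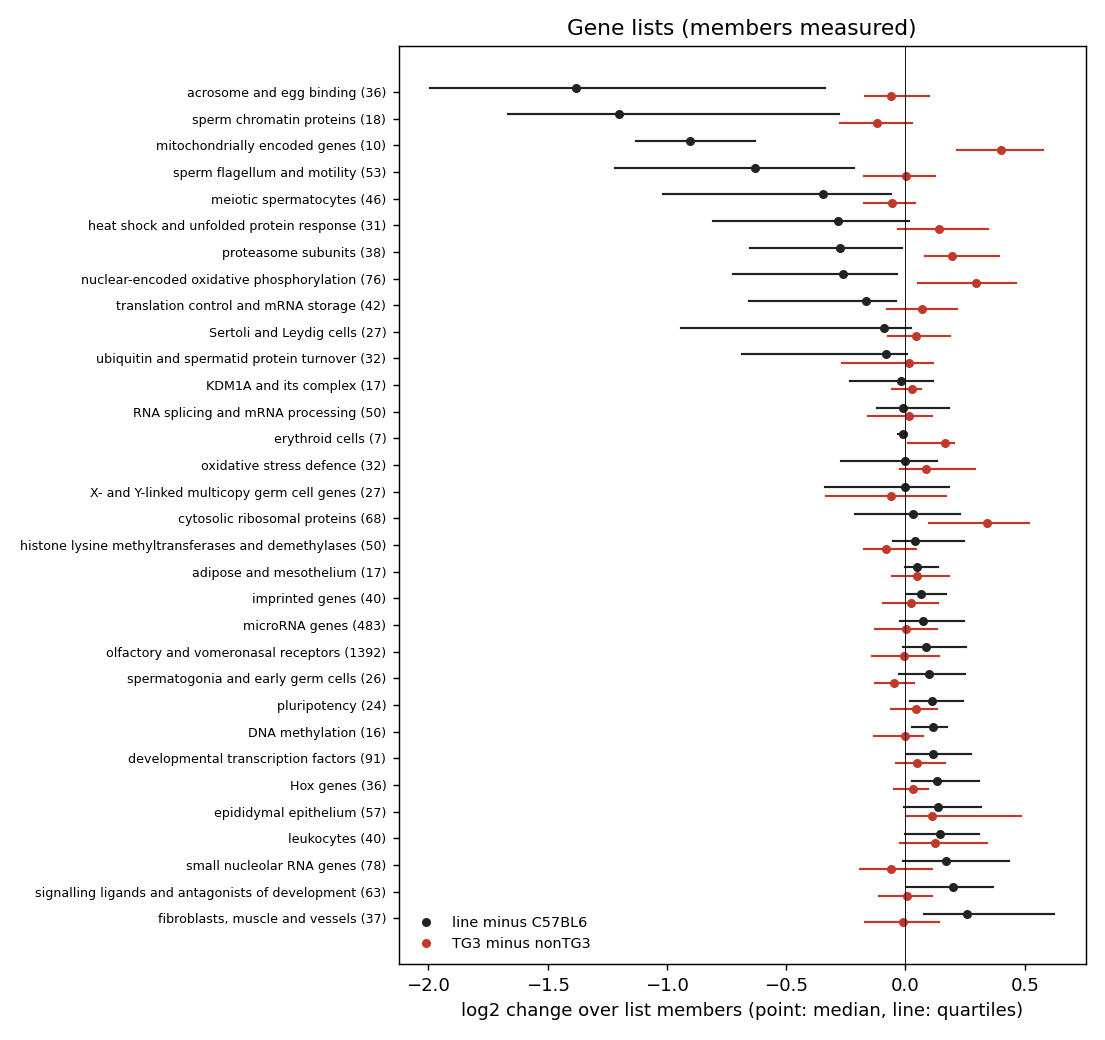
Log2 change over the members of 32 gene lists, the line minus C57BL/6 in black and TG3 minus nonTG3 in red, with a point at the median and a bar between the quartiles. The acrosome list lies lowest in the line, at -1.38, and the ribosomal protein list lies at 0.34 for TG3 minus nonTG3.

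Increases were fewer and smaller. Stx3, a membrane fusion protein, rose from 3.56 to 4.68 ± 0.06 (SD, n = 6; limma adjusted p = 0.00739). H2-Q5, Alppl2 and Trnau1ap rose by 0.84 to 1.06 log2 units, and Phf11b, C1qtnf9, Myo1g, Defa21, Psg26 and C1ql4, at 1.05 to 2.35 in C57BL/6, averaged at most 3.22 in the line. Each of these lost its call in 4 to 6 of the 6 fits that left out 1 array of the line, with adjusted p up to 0.128 (Psg26, without nonTG3 replicate 2). Of the increases 57.5% had 4 or fewer distinct values on the 6 arrays of the line, against 30.9% of all tested probe sets. Among the decreases named here, H2bc1 and Pdcl2 lost their calls without some arrays (adjusted p up to 0.0625 without TG3 replicate 2 and 0.119 without nonTG3 replicate 2), and so did Psma6 (0.108 without nonTG3 replicate 2). Without TG3 replicate 2 the count of 710 became 396, and without nonTG3 replicates 1, 2 and 3 it became 428, 350 and 438. Without both arrays with the lowest mitochondrial RNA, TG3 replicate 1 and nonTG3 replicate 3, it became 0 with 2 residual degrees of freedom, although the median change of the 670 decreases was -1.58 both with and without these arrays and the smallest adjusted p was 0.0520.

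The same contrast was made separately for carriers and for littermates. TG3 against C57BL/6 gave 595 calls, 567 lower and 28 higher. The decreases included H2bc1, Spata19, Prr27 and Dynlrb2, and also Defb19, Cst9, Cox7b2, Rasl2-9, Cyp17a1 and Tsx, which averaged below 3.52 in TG3. Defb19 read 2.88 ± 0.05 (SD, n = 3) in TG3. Spata19 read 8.97 in C57BL/6 and 4.68 ± 0.24 (SD, n = 3) in TG3. The increases included Stx3, Nrtn, a neurotrophic factor, Alppl2, Ass1, of the urea cycle, Trnau1ap, Rp1l1 and Fndc5. C1qtnf9, Defa21 and Psg26, which averaged below 3.52 in TG3, were also called higher. Nrtn read 2.84 in C57BL/6 and 3.95 ± 0.08 (SD, n = 3) in TG3. Each of these increases but Stx3 lost its call in 4 to 6 of the 6 fits that left out 1 array, with adjusted p up to 0.132 (Alppl2, without TG3 replicate 2). Camera called 15 lists, 10 lower and 5 higher, and 0 with an estimated correlation (smallest adjusted p = 0.275 with an estimated correlation). The count of 595 became 333, 272 and 330 without TG3 replicates 1, 2 and 3, 316, 300 and 333 without nonTG3 replicates 1, 2 and 3, and 0 with the TG3 and C57BL/6 arrays alone or without both arrays of lowest mitochondrial RNA. Of 69 named genes and list members, 32 lost their call without at least 1 array.

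nonTG3 against C57BL/6 gave 594 calls, 572 lower and 22 higher. The decreases included H2bc1, Dynlrb2, Spata19 and Pdcl2, and also Defb19, Cst9, Cyp17a1, Cox7b2, Rasl2-9 and Tsx, which averaged below 3.52 in nonTG3. Cyp17a1 read 2.32 ± 0.24 (SD, n = 3) in nonTG3 against 6.56. Dynlrb2 read 4.06 ± 0.46 (SD, n = 3) against 7.94. The increases included Stx3, Fndc5, Trnau1ap, Rp1l1, Rnf43 and Phf11b, which read 1.69 in C57BL/6 and 3.57 ± 0.29 (SD, n = 3) in nonTG3. C1qtnf9, Defa21, Tfb2m and Tppp, which averaged below 3.52 in nonTG3, were also called higher. Stx3 lost its call in 1 of the 6 fits that left out 1 array and each of the other increases named in 4 to 6, with adjusted p up to 0.132 (Rp1l1, without nonTG3 replicate 2). Camera called 18 lists, 12 lower and 6 higher, and 0 with an estimated correlation (smallest adjusted p = 0.322 with an estimated correlation). The count of 594 became 378 and 316 without TG3 replicates 1 and 2, 306, 228 and 294 without nonTG3 replicates 1, 2 and 3, 54 with the nonTG3 and C57BL/6 arrays alone, and 0 without both arrays of lowest mitochondrial RNA. Of 67 named genes and list members, 33 lost their call without at least 1 array.

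Of the 567 probe sets lower in TG3, 514 were also lower in nonTG3, and of the increases 18 were in both. The lists are not independent, since both were measured against the same array. In simulations of unchanged groups set against 1 control, lists of the same sizes, made of the smallest p-values in each direction, shared 217 and 4.93 on average. Independent lists would share 13.8 and 0.0262. Across probe sets the changes of TG3 and nonTG3 correlated with Pearson's r of 0.885, against 0.750 in simulations of unchanged groups set against the same single control. Their covariance was 0.194 against 0.0693 simulated. Spearman's rho was 0.675 against 0.713 and the share of equal signs 69.8% against 77.0%. Both comparisons use 1 control array that cannot be split, so part or all of the excess may come from it. The simulations let that array vary only by independent noise of the size seen between the line's pools. The difference between TG3 and nonTG3 itself was the first contrast, in which limma called 0 probe sets.

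**Figure D4:**
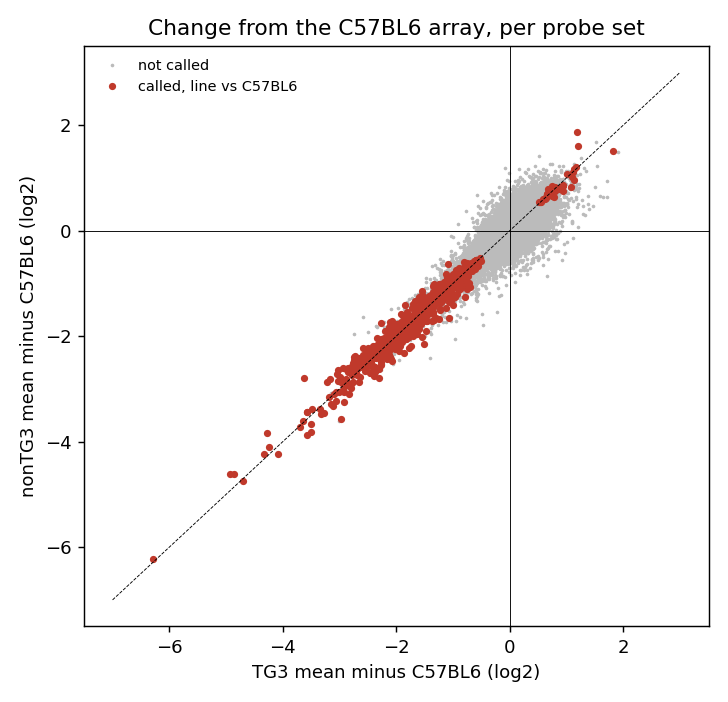
Log2 change from the C57BL/6 array for each probe set, the TG3 mean on the horizontal and the nonTG3 mean on the vertical axis, with the 710 called between the line and C57BL/6 in red and a dashed line at equal change. The decreases lie along the dashed line, with Defb19 lowest.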

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

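Probe sets with no gene symbol or with several were left out of the comparisons above. Among these 10111, limma called 6 higher and 161 lower in the line than on the C57BL/6 array, and 0 between TG3 and nonTG3. The 6 are given because they read above the control in data that the comparisons did not use. They come from a fit adjusted over all 33604 probe sets, in which 31 were higher in total. The 40 higher among the probe sets compared were adjusted over 23493, so both counts are not on the same footing. No explanation was tested for the 6. No group held 4 or more arrays, so single arrays were not tested for standing apart within a group.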

How the results depend on the processing

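The count between TG3 and nonTG3 stayed at 0 in limma under every alternative run except a looser threshold: at an unadjusted p under 0.05 and at least 1.5-fold it was 116. At that threshold the counts against C57BL/6 were 1781 for TG3, 1774 for nonTG3 and 1732 for the line, and at an adjusted p under 0.10 they were 938 for TG3 and 904 for nonTG3. Leaving out each array in turn gave 272 to 333 for TG3 against C57BL/6, 228 to 397 for nonTG3, 350 to 496 for the line, 3 to 9 lists between TG3 and nonTG3, and a correlation of both changes of 0.796 to 0.889. With the arrays of 1 kind of male and C57BL/6 alone the counts were 0 for TG3 and 54 for nonTG3. Without both arrays with the lowest mitochondrial RNA, an alternative chosen after seeing the data, they were 0, 0 and 0. Fits with fewer arrays have fewer residual degrees of freedom. With an estimated correlation camera called 0 lists in each of the 4 contrasts. fry called 0 between TG3 and nonTG3, 5 for TG3, 4 for nonTG3 and 6 for the line against C57BL/6. Other normalizations moved the count of the line against C57BL/6 to between 658 and 881. Keeping only probe sets with 5 or 6 distinct values on the line's arrays, also chosen after seeing the data, gave 480, of which 5 were higher. Over 3 other normalizations, each array left out in turn and both arrays of lowest mitochondrial RNA left out, 208 of 710 recomputed values of named genes in the line against C57BL/6 lost their call, and 0 changed direction. The cause was not tested for the other changes.

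Replicate numbers are shared by TG3 and nonTG3, but arrays with the same number did not deviate together (correlations of -0.449, 0.0159 and -0.403). The numbers thus gave no sign of pairing the pools. These correlations cannot exclude a pairing, since other differences between arrays cross the numbers (0.552 for TG3 replicate 1 and nonTG3 replicate 3). With the number as a block limma called 0 probe sets between TG3 and nonTG3 and camera called 5 lists. Arrays carry no detection calls here, so what signal over background limits was not measured.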

Other observations

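The tests of other splits of the arrays, of nonTG3 replicate 2 and of bright sperm RNAs were chosen after the results were seen. The tests of germ cell, Sertoli and Leydig cell and scale explanations were written before.

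With all arrays and probe sets camera called none of the lists not described above between the line and C57BL/6. Medians were -0.018 for KDM1A and its complex, 0.038 for histone lysine methyltransferases and demethylases, 0.12 for DNA methylation, 0.11 for pluripotency, 0.063 for imprinted genes, 0.047 for adipose and mesothelium, 0.14 for leukocytes, 0.14 for epididymal epithelium, -0.0085 for erythroid cells, 0.17 for small nucleolar RNA genes, 0.075 for microRNA genes and -0.0089 for splicing. Among their members Dpy30, of histone methyltransferase complexes, fell 3.00-fold, Ube3a, an imprinted ubiquitin ligase, fell 1.91-fold, Bpgm, an enzyme of red cell glycolysis, fell 2.76-fold, and in the epididymal list Cst12, a cystatin, fell from 5.43 to at most 2.35 on any array of the line, while Lcn8, a lipocalin, rose from 2.45 to 3.16. Of the microRNA genes Mir3083 and Mir2137 rose, from 2.94 and 6.43 to 4.60 and 7.23, and Mir468 and Mir680-1 fell, from 3.67 and 5.66 to 2.67 and 4.32. Without TG3 replicate 2 the adjusted p of Dpy30 was 0.0532, that of Bpgm was 0.0555 and that of Lcn8 was 0.0841, and without nonTG3 replicate 2 that of Ube3a was 0.101. Mir3083, Mir680-1, Mir2137 and Lcn8 lost their calls in 5, 5, 6 and 6 of the 6 fits that left out 1 array, with adjusted p up to 0.115 (Mir2137, without TG3 replicate 2). Mitochondrially encoded genes had a median of -0.90, with all 10 members lower, 0 of them called and a camera adjusted p of 0.162. They averaged 11.24 on the C57BL/6 array, 11.44, 11.51 and 11.55 on 3 arrays of the line and 8.80, 9.98 and 8.91 on the other 3, and over the alternatives run for this list the median ran from -1.26 to -0.15. X- and Y-linked multicopy genes had a median of -0.0017 and a mean of -0.28, and over probe sets with a mean at or above the median this list had a median of -1.19 and was called (adjusted p = 0.00539). Cypt4 of this list fell 4.17-fold. The lists of leukocytes, microRNA genes, small nucleolar RNA genes, pluripotency and mitochondrially encoded genes were also called under at least 1 alternative, with smallest adjusted p of 0.0216, 0.00190, 0.00293, 0.0440 and 0.0388. Ribosomal proteins had a median of 0.031 and a mean of -0.055, and Rpl10l, a testis form, fell from 3.46 to 2.01. Both readings of Rpl10l, like those of Lcn8, lay below the lowest array median of 3.52. Whether such values lie above background was not measured.

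Some RNAs of spermatids, spermatocytes, Sertoli and Leydig cells were higher on the single C57BL/6 array than in the line (17 of 36 acrosome, 8 of 46 meiotic and 6 of 27 Sertoli and Leydig genes, with adjusted p of 0.287 for each list with an estimated correlation and 0.00886 to 0.0272 with fry). After a second quantile normalization 629 decreases were called, and after cyclic loess 851, against 670 before. RMA had already brought the arrays to a common distribution. A second quantile normalization could thus change little and cannot decide on a difference in scale. The count did not fall with cyclic loess, which argues against such a difference. Equal dilution of all sperm RNA is argued against as the whole cause by 14 chromatin and flagellum genes at 9 or more on the C57BL/6 array, whose changes had an SD of 1.42 against a median standard error of 0.21 for 1 gene, but their median of -0.31 ± 0.47 (SE) and somatic medians of 0.047 to 0.26 leave dilution as a part of it open, where the highest, of fibroblasts, muscle and vessels, was 0.13 without TG3 replicate 1 and nonTG3 replicate 3. A candidate explanation is testis RNA in the C57BL/6 pool: the meiotic list had a median of -0.35, and 5 of 10 abundant Sertoli and Leydig genes fell, just reaching the bound set in advance, while Clu, Ctsl, Aard, Rhox5 and the probe set of Cyp11a1 with the higher mean did not pass. A biological difference between the line and C57BL/6 stays open and untested, since C57BL/6 has 1 array. Set alone against the rest, the C57BL/6 array gave 935 calls and no other array gave over 3. For each array of the line, however, the rest held the C57BL/6 array, which widens their spread and lowers the count. Only 1 of 7 arrays gave as many as 935, and 7 splits are too few for a share under 0.05.

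Camera at the preset correlation called the ribosomal protein, oxidative phosphorylation and proteasome lists higher in TG3 than in nonTG3, with 0 members passing and adjusted p of 0.969 with an estimated correlation and 0.814 with fry. Without nonTG3 replicate 2, an array picked after the values per array were seen, the median went from 0.34 to 0.14 ± 0.17 (SE, widened for the correlation between genes) for ribosomal proteins (0.14 to 0.48 over all 6 arrays left out in turn) and from 0.30 to 0.13 ± 0.14 for oxidative phosphorylation, while that of the proteasome list was 0.20 with and 0.19 ± 0.12 without it. The errors are too wide to decide for any of these lists. For the first pair the array picked had the lowest mean, so leaving it out had to narrow the difference. For the proteasome list nonTG3 replicate 3 was lower still, at a mean of 4.77 against 4.81. Low values on nonTG3 replicate 2 may play a part, and an effect of the transgene stays open and untested. Of the 10 splits of the 6 arrays 2 gave a ribosomal shift as large as 0.34, the highest other being 0.38, and 8 called as many lists as the real 5, the highest other being 12. These splits are too few for a share under 0.05.

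Other splits of the 6 arrays of the line also bear on the gene counts, and 10 splits are too few for a share under 0.05. All 10, the real one included, gave 0 calls, so the highest other was 0. At an unadjusted p under 0.05 the real split gave 559 and 6 of 10 gave as many. The highest other, 3532, set TG3 replicate 1 and nonTG3 replicates 2 and 3 against the rest, with 0 at adjusted p, which points to a structure of the samples, picked as the highest of 10 and not tested. Mitochondrially encoded genes averaged 8.80, 9.98 and 8.91 on these arrays and 11.44 to 11.55 on the others of the line.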
